A study of Mus musculus with 12 samples.

How the data were processed

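Scanner output of 12 Agilent 1-colour mouse 4x44k arrays (design 014868, probe positions on the mm7 build) was read per array. The values used are intensity: the background-subtracted Cy3 signal of each spot, named gProcessedSignal per the file headers. The deposited value table of the series is intensity too, on a linear scale. All columns hold 1 common set of values (column medians near 30.9), so it was quantile normalised by a method not given in the sources used here, and its Spearman correlation with the scanner values was 0.9999 to 1.000 on each array. A higher value means more signal in both. Of its 41250 lines 41174 were matched to probes. The file headers name Feature Extraction 9.5.3.1, while the submitters' processing notes name 9.1.

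Each array had 43379 non-control spots. Spots that the scanner software marked as non-uniform or as outliers among replicate spots were left out, which removed 87 probes from the comparison. Replicate spots of a probe were averaged. Values were log2 signal minus the array's 75th percentile. Probes had to be well above background on at least 3 of 12 arrays, which left 25675 probes of 17132 genes, and each gene was read from its brightest probe. Of 41174 probes 22951 were named by accession, 6659 by a current symbol and 3109 by an older symbol in a mouse gene table, and 8455 kept the name in the file. That table gave names only. No reads were aligned and no reference genome was used.

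Group means of the 4 groups were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with moderated variances (1.79 prior degrees of freedom). Each genotype effect, each LPS response and their difference, the interaction, were tested as contrasts, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each Ebf1 probe was adjusted over all probes. Where 1 group was above background on none of its arrays, a fold is given as a lower bound. With 1 or 2 of 3 arrays above background a fold is as fitted and less certain, as for Klk1b24, Pimreg, Bub1, Cdk1 and Cd80 in resting cells, Klrk1 after LPS, and Il2ra and Csf1r in the LPS response of +/fl cells. Gene lists were fixed by name: 29 lists, of which 28 were tested with camera at an inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison, and again with the correlation estimated for each list. Counts adjusted over the list alone use the members as the only tests. Lists overlap: Cr2, Cd79a, Mzb1, Ldha and others stand in more than 1.

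Named genes were set by rule: Ebf1, the 8 largest changes in each direction among genes past the threshold with non-overlapping values and with a group above background on all 3 of its arrays, and the 4 members of each list with the smallest p. Each name refers to 1 probe. Genes named under any other heading, as in the overlap of the genotype effects and at the start of the observations, were chosen after their values were seen.

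Lists, comparisons, thresholds, the rule for named genes and the first set of alternatives were chosen before the data were examined. The alternatives were normexp background correction (offset 50), quantile normalization, scaling by the median, no filter or a filter on all 12 arrays, the deposited values, slide as a fixed or random block, replicate number as a block, only the 6 arrays of a comparison, eBayes with trend and robust, array weights, the mean over a gene's probes, every probe on its own, stricter thresholds, leaving out each array, leaving out the 2 +/fl arrays whose sample names share a number, and the estimated correlation. Normexp failed on 3 arrays: 7, 20 and 16 spots with a local background above 2 times the array median gave it background standard deviations of 438, 970 and 1563 on resting fl/fl 1, resting +/fl 1 and LPS +/fl 2, against 0.42 to 3.36 elsewhere. Its values are reported as they came out. A repaired fit with the local background of those spots set to the array median was added after that was seen. Added after the data were seen as well were marker scores of macrophages and of erythroid cells as covariates, the fit without resting +/fl replicates 1 and 3, and the slide block without LPS fl/fl replicate 2. The macrophage score was the array median of the monocyte, macrophage and neutrophil list, and the erythroid score that of the erythroid list. With a score as a covariate, a change in the median of its own list is built in and tests nothing.

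Some alternatives shifted the median of all genes by more than 0.1 in places: normexp by −0.12 in the LPS genotype effect, −0.17 and −0.44 in the LPS responses of +/fl and fl/fl cells and −0.19 in the interaction, quantile normalization and the deposited values by −0.11 in fl/fl cells, no filter by 0.17, −0.22, 0.17 and 0.16 in the same order, and the repaired normexp by 0.11 in the resting genotype effect and −0.23 in both LPS responses. In the LPS response of fl/fl cells the median also moved to 0.11 with the mean over probes, the erythroid score, or without LPS fl/fl replicate 1 or 3, and to 0.12 with every probe on its own. In the values reported first every such median lay within 0.07 of 0.

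The pipeline was tested on simulated arrays with 17132 genes and known changes of 1.5-fold, 2-fold and 4-fold in 67, 67 and 66 genes, plus a list of 20 genes raised 2-fold. It recovered 14.9%, 49.3% and 78.8% in the resting genotype effect, 22.4%, 49.3% and 72.7% in the LPS genotype effect, 20.9%, 58.2% and 80.3% in the LPS response of +/fl cells, 22.4%, 58.2% and 81.8% in that of fl/fl cells, and 4.48%, 26.9% and 66.7% in the interaction. Of 16912 unchanged genes 7, 7, 12, 2 and 4 were called. The raised list was found in each comparison (p at most 5.9e-26 in 4 of them and 2.69e-23 in the interaction), and an unchanged list was not (p 0.297 to 0.948). Noise was drawn independently for each probe, with no correlation between genes and no outlying array. The simulation therefore does not show how often list or gene calls are wrong where genes vary together. The 3 arrays per group limit the precision of every comparison.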

Results

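Ebf1 is a transcription factor that sets up the B lineage and holds it in place. The series profiled splenic B cells of C57BL/6 mice that carried a tamoxifen-inducible Cre with floxed Ebf1 on both alleles (fl/fl) or on 1 allele (+/fl, the heterozygote control), so each comparison of genotypes is between animals with 2 floxed alleles and with 1, and deletion itself was not measured. Mice received tamoxifen for 4 days and were killed on day 10. Cells were measured resting or after LPS, a bacterial ligand of TLR4 that activates B cells, with 3 arrays in each of 4 groups on 3 slides of 4 arrays. The labels give no dose or time for LPS. They name 2 sorting gates, B220+AA4.1- alone or also CD21lo, without saying which samples went through which, and CD21 is the product of Cr2, so the gate itself can set Cr2 and the marginal zone genes that go with it. Beyond naming triplicates, the labels do not say whether replicates came from separate animals, so p values measure the spread between these samples, which may be technical. Numbers in the sample names also set the resting fl/fl samples apart from all others.

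LPS was the largest difference among the 12 arrays. The first principal component held 61.7% of the variance and separated all 6 resting arrays (75.1 to 88.9) from all 6 LPS arrays (−96.4 to −62.9), and the second held 10.2%. One array, LPS fl/fl replicate 2, stood apart: 83.2% of its spots were well above background, against 54.4% to 61.4% on the other arrays. Its median signal was 93.0 against 19 to 35.9, and its second component score was −92.6. Xist, the RNA that silences the X chromosome in females, differed between the genotypes by 0.33 in resting cells (adjusted p 0.342) and by −0.00 after LPS (adjusted p 0.993).

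Ebf1 RNA did not fall at both of its probes in the fl/fl cells. At the probe for the RefSeq transcript NM_007897, resting fl/fl cells read 1.81, 1.68 and 1.71 (log2 signal relative to the array's 75th percentile) and resting +/fl cells 0.75, 1.40 and 1.18. The fl/fl mean of 1.73 ± 0.07 (standard deviation) lay above the +/fl mean of 1.11 ± 0.33, a difference of 0.62 (standard error 0.15, n = 3 and 3, adjusted p 0.0382 over all probes). The probe for the longer cDNA AK036716 went the other way, with −4.21, −4.24 and −5.01 in fl/fl against −2.44, −2.18 and −3.16 in +/fl cells, a difference of −1.90 (standard error 0.49, adjusted p 0.0432). Both probes were above background on all 12 arrays. The deleted part of the allele is not given in the sources used here, so neither probe tests whether deletion took place.

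After LPS the first probe read 1.11, 1.29 and 1.22 in fl/fl and 1.17, 1.01 and 1.07 in +/fl cells (difference 0.12, adjusted p 0.673). The second read −4.38, −4.19 and −4.63 against −2.64, −4.71 and −3.08 (difference −0.92, adjusted p 0.316). LPS itself changed the first probe by −0.53 in fl/fl cells (adjusted p 0.0134) and by −0.03 in +/fl cells (adjusted p 0.897). The calls at both probes in resting cells ended with slide as a block and without the dim-probe filter, neither of which can move these values (0.62 and −1.90). They also ended, with the same signs, with a macrophage marker score as a covariate (0.45 and −2.13). Exact permutation of the labels gave p 0.1, the smallest possible with 3 and 3, for both.

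**Figure D1:**
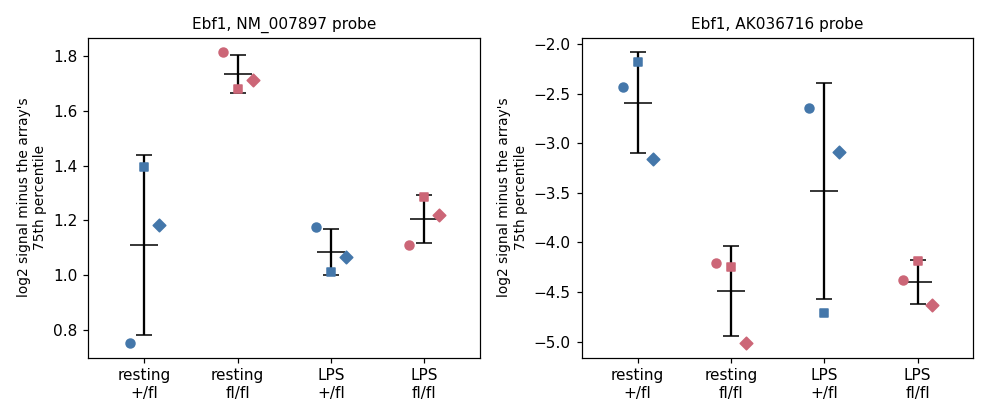
Ebf1 signal on every array at the probes for NM_007897 and AK036716. The vertical axis is log2 signal minus the array's 75th percentile for resting +/fl, resting fl/fl, LPS +/fl and LPS fl/fl cells, with circles, squares and diamonds for replicates 1, 2 and 3, a bar at the mean and error bars of 1 standard deviation. In resting cells fl/fl lies above +/fl at the first probe (1.73 against 1.11) and below it at the second (−4.49 against −2.59).

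In resting fl/fl cells 10 of 18 marginal zone and 15 of 35 cell cycle genes were lower and 5 of 14 homing genes higher than in +/fl cells. No list call held with an estimated correlation, and myeloid and erythroid markers read lower too. Cr2, the complement receptor CD21, was 5.51-fold lower (log2 −2.46, standard error 0.12, n = 3 and 3), and S1pr3, a receptor for sphingosine-1-phosphate that places B cells in the marginal zone, was 7.78-fold lower (−2.96, standard error 0.19). Cxcr4, the receptor for CXCL12, was 2.81-fold higher (1.49, standard error 0.34). Cdk1, the kinase that starts mitosis, was 9.19-fold lower (−3.20, standard error 0.66). In all, 1510 of 17132 genes passed an adjusted p of 0.05, 794 higher and 716 lower. Larger or firmer changes were mostly falls: of the 461 genes changed at least 2-fold 316 were lower, and of the 192 with an adjusted p under 0.01 only 69 were higher.

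The largest rises were in genes with no set role in B cells. Jhy, a gene of ciliated cells, was above background on all 3 resting fl/fl arrays and on no resting +/fl array (2.85 ± 0.13 against −7.17 ± 0.41, at least 271-fold higher, adjusted p 0.00029). The kallikrein Klk1b24 rose 133-fold (7.06, standard error 0.82) and its relative Klk1b21 at least 9.95-fold. Zfp30, a zinc finger protein, rose at least 6.38-fold. The largest falls were in Tsga13, a testis-specific gene (at least 25.1-fold lower), Ackr3, a scavenger receptor for CXCL12 (at least 21.7-fold), Tmem121 (20.2-fold, −4.34) and the elongation factor Ell3 (13.5-fold, −3.75, adjusted p 0.00118). Plaur, the urokinase receptor, fell 10-fold, and the mitotic genes Pimreg and Bub1 fell 12.9-fold and 9.35-fold.

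Marginal zone B cell genes moved down as a group in resting fl/fl cells: 10 of 18 fell, 1 rose and 7 did not pass (11 and 1 adjusted over the list alone), with a median of −1.53 (camera adjusted p 4.03e-09, and adjusted p = 0.0505 with an estimated correlation). Beside Cr2 and S1pr3, Asb2, part of a ubiquitin ligase, fell 4.62-fold, Mzb1, an ER protein of marginal zone B and plasma cells, 3.64-fold, and Dph5, an enzyme of diphthamide synthesis, 2.19-fold. The gate can itself set these genes. Follicular and homing genes moved up, with 5 of 14 higher and none lower (7 higher and 1 lower adjusted over the list alone, median 0.56, adjusted p 0.00595, adjusted p = 0.525 with an estimated correlation). Among them Itgb7, an integrin of gut homing, rose 1.68-fold and Gpr183, the receptor that guides B cells to follicle edges, 1.71-fold. Array medians of the marginal zone list, relative to the mean of all 12 arrays, were 1.20, 0.80 and 1.19 in resting +/fl and −0.16, −0.19 and −0.21 in resting fl/fl cells.

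Cell cycle genes moved down in resting fl/fl cells, with 15 of 35 lower, none higher and 20 not past the test (27 lower and 1 higher adjusted over the list alone, median −1.31, adjusted p 5.88e-14, adjusted p = 0.471 with an estimated correlation). E2f1, which switches on replication genes, fell 2.48-fold, Tyms, which makes thymidylate, 3.72-fold, and the mitotic kinase Aurkb 6.59-fold. MYC and ribosome biogenesis genes fell in 9 of 20 members (11 adjusted over the list alone, median −0.37, adjusted p 9.87e-07, adjusted p = 0.322 with an estimated correlation), among them Myc itself (1.85-fold) and Odc1, the first enzyme of polyamine synthesis (1.93-fold). Glycolysis genes fell in 3 of 15, Pgk1, Ldha and Tpi1 (7 lower and 1 higher adjusted over the list alone, median −0.34, adjusted p 0.00433, adjusted p = 0.322 with an estimated correlation). In germinal centre and class switching genes 3 of 11 fell and 1 rose (the same adjusted over the list alone), with a median of −0.59 (adjusted p 0.021, adjusted p = 0.549 with an estimated correlation). The 3 that fell are DNA repair genes, Apex1, Ung and Exo1 (−0.82, −0.59 and −0.90), and the 1 that rose was Bcl6, a repressor needed for germinal centres (2.40-fold).

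Markers of other blood cells differed between the same arrays. The monocyte, macrophage and neutrophil list had a median of −1.21 in resting fl/fl against +/fl cells (adjusted p 0.000344, adjusted p = 0.549 with an estimated correlation), with 1 of 15 lower, the macrophage marker Adgre1 (2.25-fold), and none adjusted over the list alone. Its array medians were 1.92, −0.09 and 1.71 in resting +/fl and 0.02, −0.44 and 0.08 in resting fl/fl cells, so +/fl replicates 1 and 3 read high. The cell cycle list followed, with 0.84, 0.02 and 1.23 against −0.81, −1.23 and −0.55, and so did erythroid markers, with 1.89, 0.21 and 1.80 against 0.69, 0.48 and −1.04. None of the 11 erythroid markers passed (median −1.10, adjusted p 0.00631, adjusted p = 0.549 with an estimated correlation). Interferon-stimulated genes had none of 17 past the test and a median of −0.96 (adjusted p 0.00121, adjusted p = 0.635 with an estimated correlation), which turned to 0.06 without +/fl replicates 1 and 3. Platelet and megakaryocyte markers had 2 of 8 higher, Itgb3 (2.93-fold) and Gp1bb (1.08), and a median of 1.14 (adjusted p 0.0218, adjusted p = 0.549 with an estimated correlation).

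**Figure D2:**
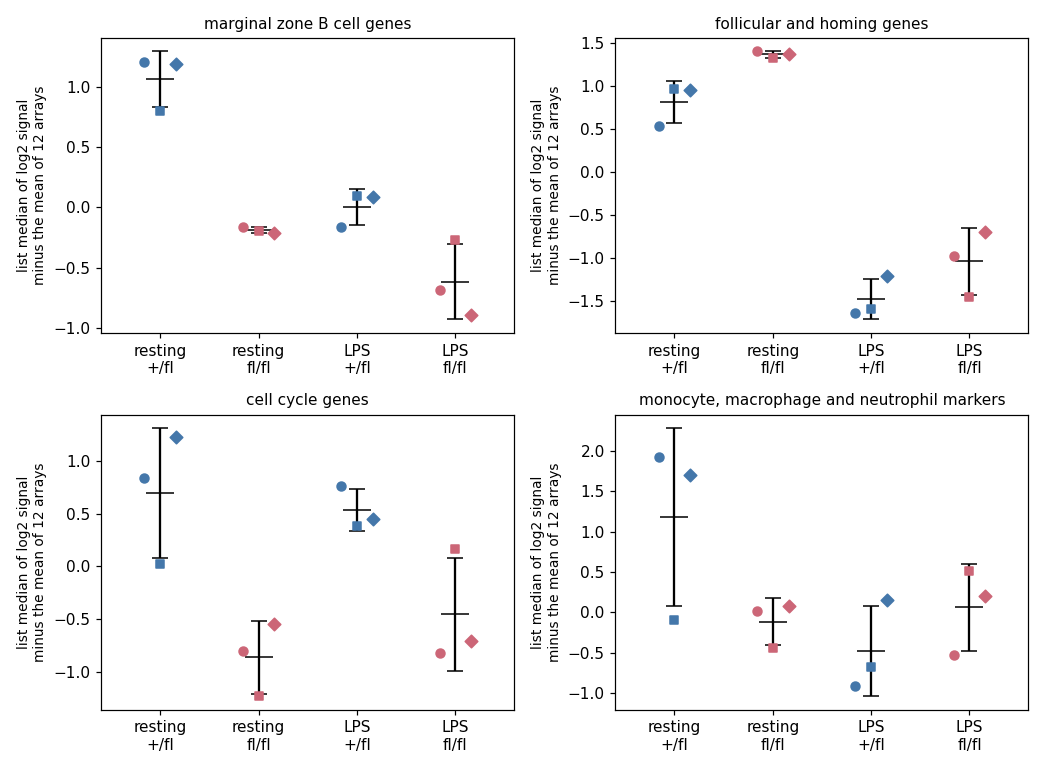
Array medians of 4 gene lists (marginal zone, follicular and homing, cell cycle, and monocyte, macrophage and neutrophil genes), as log2 signal minus the mean of the 12 arrays. Circles, squares and diamonds are replicates 1, 2 and 3, bars are means and error bars standard deviations. Resting +/fl replicates 1 and 3 read high on the myeloid list (1.92 and 1.71) and on the cell cycle list (0.84 and 1.23), while the marginal zone list is high on all 3 resting +/fl arrays (1.20, 0.80 and 1.19).

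The other 18 lists were not called in resting cells. B-lineage identity genes were split, 3 up and 3 down of 24 (4 and 4 adjusted over the list alone, median −0.11, adjusted p 0.148). Ikzf3, a lymphoid transcription factor, rose (0.74), as did Ebf1 at its brighter probe (0.62, against −1.90 at the other). Cd24a (−1.21) and the BCR signalling chain Cd79a (−0.75) were among those that fell. NF-kB and TLR response genes had 5 higher, such as the inhibitor Nfkbia (0.79) and the costimulator Cd80 (1.21), and 1 lower of 27 (7 and 2 adjusted over the list alone, median 0.07, adjusted p 0.299). In B-1 cell genes 2 of 12 rose, Spn (CD43, 2.35-fold) and Nid1 (3.17-fold), with a median of −0.14 but a mean of 0.09 (adjusted p 0.615). Immediate-early genes had 2 of 17 lower, Egr2 and Atf3 (3 adjusted over the list alone, median −0.16, adjusted p 0.0794).

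Medians and adjusted p values of the remaining lists in resting cells were 0.02 and 0.501 for BCR and co-receptor signalling (3 of 27 lower, mean −0.10), −0.21 and 0.0794 for plasma cell differentiation (1 of 14 lower, Mzb1, and 2 lower and 1 higher over the list alone). For further lists they were 0.10 and 0.541 for ER chaperones (Hyou1 higher, of 23), 0.06 and 0.676 for LPS sensing (Traf6 higher, of 13), −0.12 and 0.269 for survival and apoptosis (Bcl2a1b lower, of 20), and −0.08 and 0.501 for p53 targets (Gtse1 lower, of 14, and 2 lower and 1 higher over the list alone). They were 0.11 and 0.862 for alternative-lineage regulators (0 of 16), −0.11 and 0.082 for cholesterol synthesis (0 of 18), 0.10 and 0.269 for MHC class II and antigen presentation (Cd80 higher, of 13), −0.41 and 0.0794 for T cell markers (0 of 13), 0.08 and 0.523 for NK cell markers (0 of 11, mean −0.30), and −0.41 and 0.0584 for dendritic cell markers (Flt3 lower, of 11). Stromal and endothelial markers read −0.35 and 0.358 (Pecam1 lower, of 5), and B cell precursor markers 0.06 and 0.953 (0 of 8, mean −0.08).

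With slide as a block 1171 genes passed in resting cells. Each slide held 1 array of each resting genotype, so the block could change the spread but not the list medians. Within the 3 slides the list medians were −1.18, −1.51 and −1.38 for marginal zone genes, 0.35, 0.79 and 0.33 for follicular genes, and −0.61, −1.79 and −1.46 for cell cycle genes. They were −0.37, −0.36 and −0.33 for MYC genes, −0.05, −0.26 and −0.29 for glycolysis, and −1.0, −0.40 and −0.41 for germinal centre genes. Interferon genes read −0.46, −1.91 and −0.33, myeloid markers 0.14, −2.07 and −1.25, erythroid markers 0.32, −1.34 and −2.89, and platelet markers 1.91, 0.39 and 0.98. Non-overlapping values were seen in 31.2% of genes (5350), where 10% would do so by chance, and 4750 genes had an unadjusted p below 0.05.

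The count of 1510 fell to 0 with normexp background correction, 421 without the dim-probe filter, 276 without the 2 arrays whose sample names share a number, and 134 with only these 6 arrays in the fit. It was 192 at an adjusted p of 0.01, 86 without resting +/fl replicates 1 and 3, 73 with the macrophage score as a covariate and 477 with the erythroid score. Leaving out 1 array gave 504 (without resting fl/fl 1), 983 (fl/fl 3), 597 (+/fl 1), 747 (+/fl 3), 884 (LPS fl/fl 1), 947 (LPS +/fl 1) and 988 (LPS +/fl 3).

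After LPS fewer genes differed between the genotypes, though not in every setting: array weights gave 2728 against 1128 resting, the macrophage score 147 against 73, and leaving out resting +/fl 1 and 3 201 against 86. Il6, a cytokine that activated B cells secrete, was 4.12-fold lower in fl/fl cells (log2 −2.04, standard error 0.27, n = 3 and 3, −1.01 ± 0.51 against 1.03 ± 0.15). Cr2 was 3.95-fold lower (−1.98, standard error 0.12) and Tnfrsf13c, the BAFF receptor that keeps mature B cells alive, 3.13-fold lower (−1.65, standard error 0.15). Cd79a, the BCR signalling chain, fell 2.38-fold, and Cdt1, which licenses replication origins, 1.95-fold. Spn, the surface glycoprotein CD43, rose 2.51-fold. With slide as a block Cr2 and Tnfrsf13c kept their calls, while Il6 (−1.85, adjusted p 0.095), Cd79a (−1.39, 0.0864), Cdt1 (−0.90, 0.0864) and Spn (1.25, 0.0671) lost theirs. In all, 290 genes passed, 152 higher and 138 lower, and 131 of them changed at least 2-fold, 84 higher and 47 lower. The balance depended on the setting. It was 55 higher and 21 lower without LPS fl/fl 1, and 27 and 77 with slide as a block and LPS fl/fl 2 left out.

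The largest falls after LPS were in Ackr3 (adjusted p 0.00917, above background on 1 of 3 fl/fl arrays, so its fold is left out), Ell3 (8.61-fold, −3.11), the zinc finger gene Zfp532 (at least 2.52-fold), Ttc39c (5.04-fold) and Mybl2, a transcription factor of cycling cells (4.37-fold, −2.13). The largest rises were in the keratin Krt2 (at least 4.04-fold), Mroh2b (at least 2.61-fold), Chil5, a chitinase-like protein (at least 2.13-fold), and the muscle troponins Tnni1 (4.29-fold) and Tnnt2 (3.95-fold). Pir and Cracdl rose by 1.97 and 2.09. One of the 3 fl/fl arrays, replicate 2, read high at dim probes in general. With normexp background correction Krt2, Mroh2b, Chil5 and Pir turned lower (−0.11, −0.32, −0.51 and −0.10), but that fit failed on 3 arrays. In a repaired fit, chosen after the failure was seen, all 290 genes kept their sign and 222 their call. Krt2 then read 0.88 (adjusted p 0.0452), Mroh2b 0.73 (0.145), Chil5 0.53 (0.124) and Pir 0.79 (0.056).

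Several lists moved down in fl/fl cells after LPS. Of 24 B-lineage identity genes 3 fell and none rose (9 and 1 adjusted over the list alone, median −0.21, adjusted p 0.00262, adjusted p = 0.353 with an estimated correlation), among them Vpreb3, a surrogate light chain relative (3.58-fold), and Cnr2, the cannabinoid receptor CB2 (1.83-fold). Of 18 marginal zone genes 5 fell (7 lower and 1 higher over the list alone, median −0.35, adjusted p 0.000264, adjusted p = 0.269 with an estimated correlation), with the tetraspanin Cd9 at 3.11-fold, Mzb1 at 2.87-fold and Dtx1, a Notch pathway gene, at 2.14-fold. The gate can set these genes here too. Cell cycle genes fell in 5 of 35 (12 over the list alone, median −0.78, adjusted p 9.21e-12, adjusted p = 0.353 with an estimated correlation), namely Cdt1, Mcm2, the helicase parts Mcm4 (−0.70) and Mcm7 (−0.77) and cyclin E1 (Ccne1, 3.09-fold). The number of members lower was 0 with slide as a block, 9 without LPS fl/fl replicate 2 (median −0.97) and 9 with both (median −1.42).

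Genes of growth and metabolism read lower as well. MYC and ribosome genes fell in 2 of 20, Ldha and Pes1 (5 over the list alone, median −0.24, adjusted p 2.07e-06, adjusted p = 0.333 with an estimated correlation). Glycolysis genes fell in 4 of 15, with Tpi1, the triose phosphate isomerase, at 1.70-fold (5 over the list alone, median −0.31, adjusted p 0.000106, adjusted p = 0.269 with an estimated correlation). No cholesterol synthesis gene of 18 passed (2 lower over the list alone, median −0.26, adjusted p 0.000256, adjusted p = 0.426 with an estimated correlation), with Mvd at −0.59 (adjusted p 0.0661). The ER chaperone list, with 0 of 23 past the test, had a median of −0.12 (adjusted p 0.0139, adjusted p = 0.425 with an estimated correlation) that turned to 0.0013 with quantile normalization and 0.0012 in the deposited values.

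Other lists moved up after LPS. Of 14 p53 targets none passed (3 higher over the list alone, median 0.47, adjusted p 0.0114, adjusted p = 0.452 with an estimated correlation), and Mdm2, the ligase that degrades p53, read 0.62 (adjusted p 0.0814). MHC class II genes had 0 of 13 past the test (4 higher over the list alone, median 0.28, adjusted p 0.00192, adjusted p = 0.387 with an estimated correlation). Interferon-stimulated genes had 0 of 17 (median 0.71, adjusted p 0.00201, adjusted p = 0.509 with an estimated correlation). Markers of other cells were higher too. NK cell markers had 1 of 11 higher, the receptor Klrk1 at 2.71-fold (−0.34 as log2 with normexp and 0.59 with the repaired fit, 10 over the list alone, median 1.11, adjusted p 3.53e-06, adjusted p = 0.334 with an estimated correlation). T cell markers had 0 of 13 past the test (1 higher over the list alone, median 0.62, adjusted p 0.00663, adjusted p = 0.509 with an estimated correlation). Dendritic cell markers had 1 of 11 higher, Siglech at 3.11-fold (3 over the list alone, median 0.59, adjusted p 0.0239, adjusted p = 0.426 with an estimated correlation). Stromal and endothelial markers had 0 of 5 (1 higher over the list alone, median 0.91, adjusted p 0.0406, adjusted p = 0.353 with an estimated correlation). Without LPS fl/fl replicate 2 the stromal median was 0.23 (adjusted p 0.113), and the dendritic (0.45, adjusted p 0.0679) and ER chaperone (−0.12, adjusted p 0.113) calls ended as well.

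The remaining 14 lists were not called after LPS. Follicular and homing genes had Itgb7 higher (3 higher and 1 lower of 14 over the list alone, median 0.37, adjusted p 0.0833). Survival genes had Bcl2 and its antagonist Bcl2l11 higher and Tnfrsf13c lower (3 and 1 of 20 over the list alone, median 0.19, adjusted p 0.446). B-1 genes had Spn higher and Ahr (3.35-fold) and Plscr1 lower of 12 (median 0.26, mean −0.05, test down, adjusted p 0.6), and NF-kB genes had Il6 lower (2 of 27 over the list alone, median 0.08, mean −0.17, test down, adjusted p 0.451). Il10, a cytokine that damps inflammation, read −1.74 (adjusted p 0.0724). Immediate-early genes had 0 of 17 past the test (1 lower over the list alone, median 0.13, test down, adjusted p 0.956).

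Elsewhere after LPS the medians and adjusted p values were −0.03 and 0.44 for BCR signalling (Cr2 and Cd79a lower, of 27, and 4 lower and 2 higher over the list alone). They were −0.49 and 0.184 for germinal centre genes (0 of 11), −0.05 and 0.127 for plasma cell genes (Mzb1 lower, of 14), −0.00 and 0.451 for LPS sensing (0 of 13, and 1 lower over the list alone) and 0.44 and 0.451 for alternative-lineage regulators (0 of 16, and 3 higher and 3 lower over the list alone). Among markers they were 0.75 and 0.0528 for myeloid cells (0 of 15), −0.62 and 0.174 for erythroid cells (0 of 11, and 2 lower over the list alone), 0.78 and 0.0677 for platelets (0 of 8) and 0.57 and 0.125 for B cell precursors (0 of 8, and 1 higher over the list alone).

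Slide and genotype were partly mixed after LPS, since only slide 2 held both LPS genotypes. With slide as a block 5 genes passed in place of 290, or 104 when LPS fl/fl replicate 2 was left out too. Blocked list medians, with the slide 2 value second, were −0.06 and −0.11 for B-lineage genes, −0.44 and −0.52 for marginal zone genes, −1.15 and −1.40 for cell cycle genes, −0.31 and −0.33 for MYC genes, −0.18 and −0.00 for cholesterol synthesis, −0.42 and −0.47 for glycolysis and −0.13 and −0.08 for ER chaperones. They were 0.39 and 0.32 for p53 targets, 0.53 and 1.36 for interferon genes, 0.41 and 0.54 for MHC class II, 0.08 and 0.31 for T cell markers, 0.80 and 0.62 for NK cell markers, 0.53 and 0.21 for dendritic cell markers and 1.10 and 0.46 for stromal markers. The block ended the calls of the interferon (adjusted p 0.116), T cell (0.697), dendritic (0.168) and stromal (0.231) lists. It added calls of platelet markers (1.61, adjusted p 0.011) and plasma cell genes (−0.20, adjusted p 0.0135), and the B-1 median went from 0.26 to −0.61 (adjusted p 0.107). Without LPS fl/fl replicate 2 as well, the B-lineage (0.01, adjusted p 0.0828), cholesterol (−0.09, adjusted p 0.0862) and ER chaperone (−0.13, adjusted p 0.0863) calls ended too. Called there were also follicular (0.46, adjusted p 0.0115), B-1 (−1.02, 0.017), plasma cell (−0.19, 0.017), erythroid (−0.82, 0.0218) and platelet lists (1.03, 0.0115). With normexp, the fit that failed on 3 arrays, the medians of the B-lineage (0.07), ER chaperone (0.29), MYC (0.21), cholesterol (0.15), glycolysis (0.05) and stromal (−0.59) lists turned sign, and none of them did in the repaired fit. Non-overlapping values were seen in 33.4% of genes (5717, where 10% would by chance), and 3681 genes had an unadjusted p below 0.05.

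The count of 290 became 0 with normexp, 411 with the repaired normexp (167 higher and 244 lower), 136 with quantile normalization (40.4% higher in place of 52.4%) or the deposited values (39.7% higher), and 27 without the dim-probe filter. It was 531 with probes above background on all arrays, 642 with trend and robust variances, 2728 with array weights, 14 without the arrays sharing a number, 147 with the macrophage score, 32 with only these 6 arrays and 15 at an adjusted p of 0.01. Leaving out 1 array gave 93 (without resting fl/fl 3), 177 (resting +/fl 3), 76 (LPS fl/fl 1), 116 (LPS fl/fl 3), 77 (LPS +/fl 1), 38 (LPS +/fl 2) and 16 (LPS +/fl 3).

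The genotype effects overlapped in part between resting and LPS cells, which share no arrays. They may share an animal, since the names of a resting and an LPS +/fl sample hold the same number. Fewer genes were shared without those arrays. Ackr3, Ell3, Cr2, Mzb1, Mybl2, Asb2 and Cd79a were lower and Spn and Itgb7 higher in both states. Together 27 genes were higher in both (7.04 expected from the counts alone) and 55 lower in both (5.77 expected), while 5 were called in opposite directions. Both effects use the same estimate of spread for a gene, so genes with a small spread pass more easily in both. The expected numbers are therefore likely too low. Over all genes the 2 effects correlated at 0.15 (jackknife error 0.16), and over the genes called in resting cells at 0.58, with 71.7% of them sharing their sign. The 82 shared genes became 3 with slide as a block, 0 with normexp, 11 without the dim-probe filter and 11 with the macrophage score as a covariate.

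LPS changed more than 0.5 of the measured genes in either genotype. In +/fl cells Il6 rose at least 76.8-fold, Srm, which makes spermidine, 9.92-fold (log2 3.31, standard error 0.15, n = 3 and 3) and Cdkn1a, the p53-driven inhibitor of cyclin-dependent kinases, 140-fold (7.13, standard error 0.28). Ciita, the master activator of MHC class II genes, fell 31.4-fold (−4.97, standard error 0.18) and Itgb7 30.1-fold (−4.91, standard error 0.12). The same genes moved the same way in fl/fl cells: Il6 rose at least 18.3-fold and Cdkn1a 257-fold, and Ciita fell 28.6-fold and Itgb7 32.7-fold. In +/fl cells 9891 genes passed, 5201 higher and 4690 lower, and in fl/fl cells 9524, 5116 higher and 4408 lower, with 5655 and 5272 changed at least 2-fold. The balance of directions depended on the processing: it turned to 4828 higher and 6632 lower in +/fl and 4369 and 6854 in fl/fl cells with the repaired normexp, and to 4504 and 5003 in fl/fl cells with quantile normalization.

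Among the largest rises were Phlda3, a p53 target that restrains AKT (284-fold in +/fl, 444-fold in fl/fl), the IL-2 receptor chain Il2ra (145-fold and at least 183-fold), the Wnt ligand Wnt10b (at least 30-fold and at least 38.2-fold) and Inka2 (at least 38.8-fold and at least 55.7-fold). The largest falls in +/fl cells were in macrophage genes, C1qc and C1qa of the complement C1 complex (at least 151-fold and at least 103-fold), Vcam1, an adhesion molecule (at least 95.2-fold), and Csf1r, the receptor for the macrophage growth factor (107-fold). In fl/fl cells C1qc fell at least 95.4-fold and Csf1r 19.8-fold, and the list of largest falls also held Jhy (above background on 2 of 3 LPS arrays), Klk1b24 (at least 136-fold) and Fos, an immediate-early transcription factor (−6.11).

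Growth programmes rose in both genotypes. All 20 MYC and ribosome genes rose in each (median 2.30 in +/fl, adjusted p 7.94e-12, adjusted p = 0.115 with an estimated correlation, and 2.48 in fl/fl, adjusted p 2.01e-12, adjusted p = 0.16 with an estimated correlation), for example Rrp9 (2.72 and 2.82) and Cad, the entry enzyme of pyrimidine synthesis (2.74 and 2.75). Cholesterol synthesis genes rose in 18 and 17 of 18 (medians 2.28 and 2.04, adjusted p 3.31e-08 and 9.29e-08, adjusted p = 0.203 and adjusted p = 0.195 with an estimated correlation), with Fdps at 3.29 and 3.31 and Idi1 at 3.75 and 3.47. NF-kB and TLR response genes rose in 21 and 17 of 27 and fell in 1 and 2 (20 and 2 in fl/fl over the list alone, medians 1.42 and 1.28, adjusted p 4.8e-07 and 2.07e-05, adjusted p = 0.115 and adjusted p = 0.16 with an estimated correlation), such as Traf1 (2.99 and 2.70).

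Genes of p53 and of survival also rose. Of 14 p53 targets 11 rose and 1 fell in +/fl and 12 and 1 in fl/fl cells (medians 2.87 and 3.13, adjusted p 8.41e-05 and 8.73e-06, adjusted p = 0.203 and adjusted p = 0.16 with an estimated correlation), among them Aen, a nuclease of apoptosis (2.91 and 2.97), and Ccng1 (2.44 and 2.67). Survival and apoptosis genes rose in 11 and 14 of 20 and fell in 2 and 4 (5 in fl/fl over the list alone, medians 0.46 and 0.98, adjusted p 0.0156 and 0.0135, adjusted p = 0.199 and adjusted p = 0.16 with an estimated correlation). The list mixes both directions of cell fate: the protective Bcl2l1 rose by 4.76 and 4.93 and Bcl2a1b by 3.05 and 3.69, and the death genes Bbc3 (PUMA) by 3.94 and 4.30 and Bax by 2.93 and 3.28.

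Genes of the resting B cell fell. MHC class II and antigen presentation genes fell in 11 of 13 and rose in 2 in each genotype (medians −3.20 and −2.90, adjusted p 2.88e-05 and 1.98e-05, adjusted p = 0.203 and adjusted p = 0.16 with an estimated correlation), with H2-Oa at −5.57 and −5.50 and H2-DMa, which loads peptides, at −3.33 and −2.90. BCR and co-receptor genes fell in 20 and 21 of 27 and rose in 1 and 3 (medians −1.34 and −1.52, adjusted p 5.1e-07 and 4.37e-07, adjusted p = 0.199 and adjusted p = 0.16 with an estimated correlation). B-lineage genes fell in 16 and 17 of 24 and rose in 2 and 2 (medians −1.05 and −1.51, adjusted p 3.82e-05 and 6.44e-06, adjusted p = 0.199 and adjusted p = 0.16 with an estimated correlation), with Cd79a at −2.93 and −3.43. Follicular genes fell in 10 and 10 of 14 and rose in 3 and 2 (medians −2.41 and −2.30, adjusted p 0.00172 and 0.000209, adjusted p = 0.203 and adjusted p = 0.16 with an estimated correlation), with S1pr1, the exit receptor, at −4.51 and −4.60.

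Other lists were called in +/fl cells but not in fl/fl cells, which is no test that the genotypes differ. Marginal zone genes had 4 higher and 10 lower of 18 in +/fl (median −0.56, adjusted p 0.0255, adjusted p = 0.268 with an estimated correlation) and 4 and 8 in fl/fl cells (−0.59, adjusted p 0.195). S1pr3 fell by 4.38 in +/fl and by 1.76 in fl/fl cells. ER chaperones had 15 higher and 3 lower of 23 (median 0.64, adjusted p 0.0156, adjusted p = 0.274 with an estimated correlation), with Canx, calnexin, at 1.68, against 15 and 5 in fl/fl cells (0.46, adjusted p 0.195). Immediate-early genes had 2 higher and 12 lower of 17 in +/fl (3 and 12 over the list alone, median −2.06, adjusted p 0.0122, adjusted p = 0.595 with an estimated correlation) and 3 and 11 in fl/fl cells (4 and 11 over the list alone, −1.73, adjusted p 0.0513).

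Markers of other cells fell with LPS in +/fl cells. NK cell markers fell in 11 of 11 in +/fl and 10 of 11 in fl/fl cells (medians −3.47 and −1.86, adjusted p 2.88e-05 and 0.00193, adjusted p = 0.203 and adjusted p = 0.378 with an estimated correlation), with Nkg7, a granule protein, at −3.81 and −2.85. Platelet markers fell in 7 of 8 in each (medians −3.00 and −3.39, adjusted p 0.00612 and 0.00193, adjusted p = 0.268 and adjusted p = 0.239 with an estimated correlation). Myeloid markers fell in 7 of 15 in +/fl cells (median −0.91, adjusted p 0.0226, adjusted p = 0.595 with an estimated correlation), with 6 higher and 5 lower in fl/fl cells (median 0.14, mean −0.30, adjusted p 0.627). T cell markers fell in 6 of 13 in +/fl (median −0.84, adjusted p 0.014, adjusted p = 0.595 with an estimated correlation), with 1 higher and 3 lower in fl/fl cells (0 and 2 over the list alone, −0.04, adjusted p 0.585). With the macrophage score as a covariate the myeloid median in +/fl cells turned to 0.38, which tests nothing, since the score is the array median of that list.

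The 12 lists called in neither response had mixed members. Cell cycle genes had 7 higher and 4 lower of 35 in +/fl (5 and 3 over the list alone, median −0.16, test up, adjusted p 0.942) and 9 and 5 in fl/fl cells (median 0.45, adjusted p 0.585), with cyclin D2 (Ccnd2) at 3.66 and 4.58 and E2f2 at −1.55 and −2.21. Plasma cell genes had 5 higher and 3 lower of 14 in +/fl (median −0.22, test up, adjusted p 0.942) and 5 and 2 in fl/fl cells (0.14, adjusted p 0.707), with Irf4 at 1.73 and 1.79 and Sdc1 (CD138) at −2.08 and −2.41. Germinal centre genes had 5 and 2 of 11 in each (5 and 3 in fl/fl over the list alone), with medians of −0.13 and −0.03 and means of 0.31 and 0.57 (adjusted p 0.314 and 0.281). Interferon genes had 4 higher and 6 lower of 17 in +/fl (median −0.78, adjusted p 0.484) and 8 and 1 in fl/fl cells (9 and 1 over the list alone, 1.45, adjusted p 0.062), with Cxcl10 at 4.53 and 5.99.

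Glycolysis genes had 10 higher and 3 lower of 15 and then 9 and 3 (medians 0.88 and 0.75, adjusted p 0.0549 and 0.09), with hexokinase 2 (Hk2) at 3.81 and 4.24. B-1 genes had 5 and 2 of 12 and then 5 and 1 (0.35 and −0.01, adjusted p 0.352 and 0.585), LPS sensing genes 5 and 5 of 13 and then 6 and 6 (−0.10 and −0.22, adjusted p 0.942 and 0.819), with Tlr4 at −2.55 and −2.31. Alternative-lineage regulators had 2 and 8 of 16 and then 3 and 6 (−0.49 and −0.44, adjusted p 0.314 and 0.495). Dendritic markers had 3 and 8 of 11 and then 3 and 3 (3 and 4 over the list alone, −2.10 and −0.43, adjusted p 0.109 and 0.672). Erythroid markers had 2 and 6 of 11 and then 1 and 2 (1 and 0 over the list alone, −2.12 and −0.64, adjusted p 0.289 and 0.672). Stromal markers had 0 and 3 of 5 and then 1 and 2 (−1.84 and −0.49, adjusted p 0.0888 and 0.503). Precursor markers had 2 and 2 of 8 in each (1 and 2 in +/fl over the list alone, −0.54 and −0.05, with a mean of 0.05 in fl/fl, adjusted p 0.511 and 0.898).

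**Figure D3:**
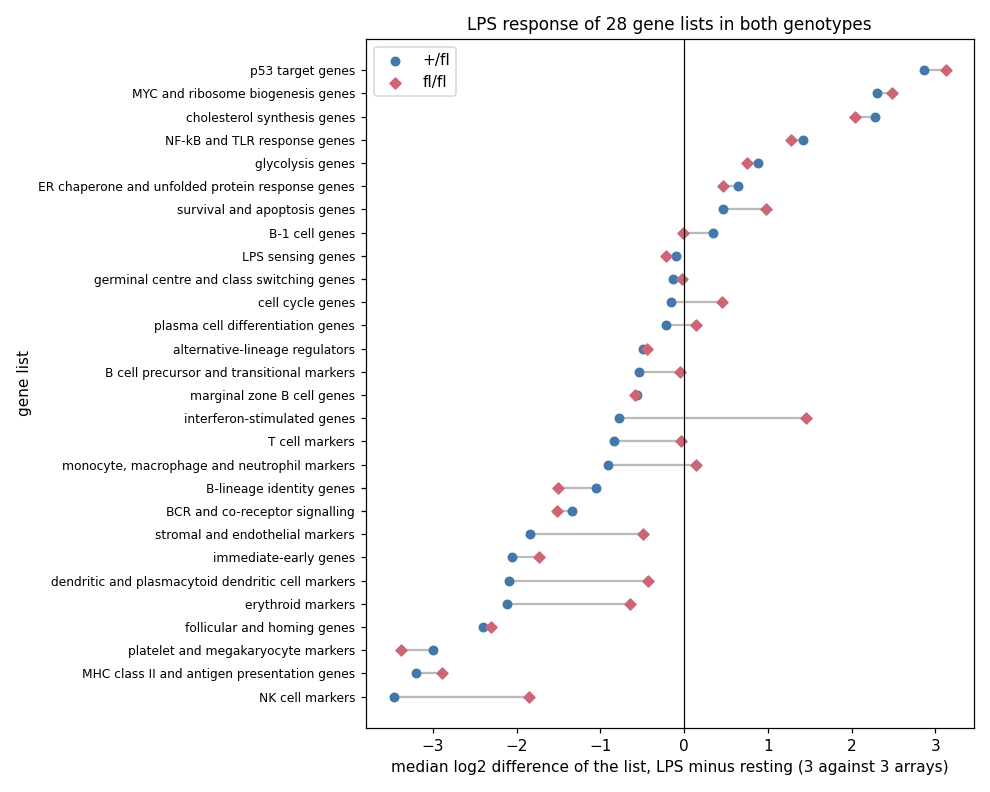
Median log2 change with LPS of each of the 28 gene lists, LPS minus resting, with blue circles for +/fl and red diamonds for fl/fl cells. MYC, cholesterol synthesis and p53 lists lie far above 0 and MHC class II and follicular lists far below 0 in both genotypes, while the interferon list (−0.78 and 1.45) and the myeloid list (−0.91 and 0.14) lie on opposite sides of 0.

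With slide as a block the medians in +/fl and fl/fl cells were 2.41 and 2.43 for MYC genes, 2.26 and 2.04 for cholesterol synthesis, 2.92 and 3.11 for p53 targets, 1.32 and 1.29 for NF-kB genes, 0.44 and 0.97 for survival genes. The falling lists had −3.29 and −2.88 for MHC class II, −1.43 and −1.46 for BCR genes, −1.09 and −1.47 for B-lineage genes, −2.48 and −2.17 for follicular genes, −3.28 and −1.99 for NK cell markers and −3.34 and −3.21 for platelet markers. In +/fl cells they were −0.60 for marginal zone genes, 0.68 for ER chaperones, −2.11 for immediate-early genes, −0.45 for T cell markers and −0.53 for myeloid markers.

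Within slides 1 and 2 the +/fl medians were 2.43 and 2.20 for MYC genes, 2.20 and 2.02 for cholesterol synthesis, 2.92 and 3.07 for p53 targets, 1.09 and 1.66 for NF-kB genes, 0.49 and 0.56 for survival genes. They were −3.34 and −3.15 for MHC class II, −1.58 and −1.14 for BCR genes, −1.26 and −0.91 for B-lineage genes, −2.29 and −2.09 for follicular genes and −0.54 and −0.99 for marginal zone genes. Next came 0.72 and 0.61 for ER chaperones, −2.75 and −0.82 for immediate-early genes, −3.26 and −3.62 for NK, −3.29 and −3.47 for platelet, −0.04 and −0.93 for T cell and −0.00 and −3.05 for myeloid markers. Within slides 2 and 3 the fl/fl medians were 2.22 and 2.49 for MYC genes, 2.19 and 1.88 for cholesterol synthesis, 3.1 and 3.09 for p53 targets, 1.34 and 1.49 for NF-kB genes, 0.74 and 1.25 for survival genes. The falling lists there had −2.76 and −3.06 for MHC class II, −1.38 and −1.53 for BCR genes, −1.36 and −1.41 for B-lineage genes, −2.02 and −2.46 for follicular genes, −2.67 and −1.52 for NK and −3.02 and −2.39 for platelet markers.

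The 2 LPS responses shared most of their genes: 4190 were higher in both (1553 expected from the counts alone), 3487 lower in both (1207 expected) and 30 called in opposite directions, with a correlation of 0.83 over all genes and no arrays in common. These expected numbers, too, ignore that both responses use the same estimate of spread for a gene. Non-overlapping values were seen in 65.7% of genes in +/fl (11259) and 62.1% in fl/fl cells (10647), where 10% would by chance. With normexp 1484 and 2390 genes passed, with 1325 shared.

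The difference between the genotypes in their LPS response was tested directly and passed for 30 genes, 18 higher and 12 lower in fl/fl cells, a balance that depended on the setting. S1pr3 gave 2.61 (standard error 0.27, adjusted p 0.00735), since it was lower in resting fl/fl cells and near the same low level in both genotypes after LPS. Plaur, the urokinase receptor, followed the same course (3.54, adjusted p 0.0115). Nebl, an actin-binding protein, was lower in resting fl/fl cells and rose to a like level in both genotypes (−4.79 to −1.59 in fl/fl, −2.01 to −1.52 in +/fl, interaction 2.71, adjusted p 0.00279). An immunoglobulin heavy chain probe named Igh rose in fl/fl (−4.57 to −3.31) and fell in +/fl cells (−1.96 to −3.28, interaction 2.58, adjusted p 0.00735). Jhy was above background on 0 of 3 arrays in both +/fl groups, so its interaction (−7.76, adjusted p 0.0344) rests on its fall in fl/fl cells and has no exact size. Atp10d, a lipid flippase, was higher in resting fl/fl cells (0.91, adjusted p 0.00321) and lower after LPS (−0.88, adjusted p 0.00977), an interaction of −1.79 (adjusted p 0.00271). Tlr3, a receptor for double-stranded RNA, was lower resting (−1.70) and higher after LPS (1.39), an interaction of 3.09 (adjusted p 0.0113) that has no exact size, since 0 of 3 LPS +/fl arrays were above background. It turned to −0.29 with normexp but was 0.92 (adjusted p 0.0439) in the repaired fit, where all 30 genes kept their sign and 27 their call.

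Of the lists, 9 were called in the interaction. Marginal zone genes had 1 of 18 higher (6 higher and 2 lower over the list alone, median 0.75, adjusted p 0.00185, adjusted p = 0.494 with an estimated correlation). Interferon-stimulated genes had 0 of 17 past the test (9 higher over the list alone, median 1.55, adjusted p 3.17e-06, adjusted p = 0.579 with an estimated correlation). None of the 14 p53 targets passed (1 higher over the list alone, median 0.36, adjusted p 0.0193, adjusted p = 0.607 with an estimated correlation), nor any of the 23 ER chaperones (median −0.16, adjusted p 0.039, adjusted p = 0.579 with an estimated correlation), whose median turned to 0.06 with quantile normalization.

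Markers of other cells moved in the interaction too. Myeloid markers had 0 of 15 past the test (3 higher over the list alone, median 2.28, adjusted p 5.25e-05, adjusted p = 0.579 with an estimated correlation). NK cell markers had 0 of 11 (5 higher over the list alone, median 1.42, adjusted p 5.36e-05, adjusted p = 0.494 with an estimated correlation). T cell markers had 0 of 13 (median 0.96, adjusted p 0.000863, adjusted p = 0.607 with an estimated correlation). Dendritic markers had 0 of 11 (4 higher over the list alone, median 1.20, adjusted p 0.00105, adjusted p = 0.494 with an estimated correlation). Stromal markers had 0 of 5 (3 higher over the list alone, median 0.88, adjusted p 0.0393, adjusted p = 0.494 with an estimated correlation). With the macrophage score as a covariate the interferon median fell to 0.44. The myeloid median turned to −0.03, which tests nothing, since the score is the array median of that list.

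In the other 19 lists no member passed in the interaction. Medians and adjusted p values were −0.27 and 0.212 for B-lineage genes, 0.03 and 0.968 for BCR genes, −0.21 and 0.248 for follicular genes, 0.02 and 0.304 for B-1 genes (mean −0.14, test down). The next were 0.16 and 0.309 for germinal centre genes, 0.25 and 0.65 for plasma cell genes, 0.38 and 0.298 for cell cycle genes, −0.29 and 0.131 for NF-kB genes, −0.03 and 0.352 for LPS sensing, 0.34 and 0.212 for survival genes and 0.10 and 0.664 for alternative-lineage regulators. They were 0.34 and 0.202 for immediate-early genes, 0.05 and 0.421 for MYC genes, −0.17 and 0.248 for cholesterol synthesis, −0.13 and 0.491 for glycolysis, 0.14 and 0.248 for MHC class II, 0.65 and 0.298 for erythroid, −0.50 and 0.421 for platelet and 0.49 and 0.298 for precursor markers. Over the list alone some members passed, higher and lower: 3 and 4 of the B-lineage genes, 0 and 1 of the follicular genes, 0 and 4 of the B-1 genes, 0 and 1 of the cell cycle genes, 1 and 5 of the NF-kB genes, 1 and 1 of the survival genes and 0 and 1 of the platelet markers.

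Il6, which differed between the genotypes after LPS, gave −2.06 in the interaction (adjusted p 0.0635). With slide as a block 7 genes passed in place of 30. The medians were then 0.64 for marginal zone genes, −0.17 for ER chaperones, 0.40 for p53 targets, 1.14 for interferon genes, 2.18 for myeloid, 0.98 for NK, 0.44 for T cell, 1.14 for dendritic and 0.72 for stromal markers, which lost their call (adjusted p 0.0896). On slide 2, the only one with all 4 groups, the medians were 0.68 for marginal zone genes, −0.26 for ER chaperones, 0.26 for p53 targets, 3.50 for interferon genes, 3.28 for myeloid, 0.87 for NK, 0.77 for T cell, 1.46 for dendritic and 0.29 for stromal markers. The resting +/fl array on slide 2 was replicate 1, with an interferon median of 1.16 and a myeloid median of 1.92. Replicates 2 and 3 read −0.31 and 0.03 for interferon genes and −0.09 and 1.71 for myeloid markers. The slide 2 values of these lists depend on that array, so they are no separate check. An unadjusted p below 0.05 was reached by 3486 genes.

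The count of 30 became 0 with normexp or the macrophage score, 17 with the erythroid score, and 8 without the dim-probe filter. It was 238 with probes above background on all arrays (96 higher and 142 lower), 424 with trend and robust variances (150 and 274), 326 with array weights (139 and 187), 7 with probe means, 3 without the arrays sharing a number, 100 with the normexp fit whose background was repaired (42 and 58), and 5 at an adjusted p of 0.01. Leaving out 1 array gave 13 (without resting fl/fl 2), 18 (resting fl/fl 3), 140 (resting +/fl 2), 16 (resting +/fl 3), 14 (LPS fl/fl 3), 8 (LPS +/fl 1), 13 (LPS +/fl 2) and 10 (LPS +/fl 3).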

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

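The tests on chromosome 11 and on regrouping the arrays were written before the results were seen. Those on marker scores and on LPS fl/fl replicate 2 were chosen after the result was seen.

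In 30 genes the genotypes differed in their LPS response. The response was higher in fl/fl cells, as log2 differences of the responses, for Tsga13 (7.15), Tfr2 (4.38), Plaur (3.54), Tlr3 (3.09), Nebl (2.71), S1pr3 (2.61), Igh (2.58) and Cln8 (2.46). It was lower for Jhy (−7.76), Psd3 (−3.04), Lrrc23 (−2.11), Atp10d (−1.79), Tmem210 (−1.40), Adat2 (−1.36), Nr2f6 (−1.09) and Ubxn7 (−0.94). These sizes are not exact for Tsga13 (above background on 0 of 3 resting fl/fl and 0 of 3 LPS +/fl arrays), Tfr2 (1 and 0 of 3), Tlr3 (0 of 3 LPS +/fl arrays) and Jhy (0 of 3 in both +/fl groups). Among lists the median difference was 0.75 for marginal zone genes, −0.16 for ER chaperones, 0.36 for p53 targets, 1.55 for interferon-stimulated genes, 0.96 for T cell, 1.42 for NK cell, 2.28 for monocyte, macrophage and neutrophil, 1.20 for dendritic and 0.88 for stromal and endothelial markers. All 9 of these list calls ended with an estimated correlation (adjusted p 0.494 to 0.607), and with the macrophage score no gene passed. The myeloid median was then −0.03, which tests nothing, since the score is the array median of that list. Among 100 of the 200 ways to split the arrays evenly within each state, 3 gave at least as many genes, the real one included, with 155 at most, and this share is under 5%. The splits with 155, 42 and 28 genes kept the real resting groups and mixed the LPS arrays, so they are not free of the genotype difference. Splits that mix the resting groups put the resting genotype difference into the spread, which lowers their counts. The share under 5% thus cannot decide whether the genotype effect differs between the states.

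Resting +/fl replicates 1 and 3 carry high myeloid and erythroid marker signal, and the lower cell cycle RNA of resting fl/fl cells might come from dividing myeloid or erythroid cells in those samples. The erythroid score moved the count of called genes from 1510 to 477 and left the cell cycle median at −1.28 of −1.31. That is 3.71 times the median standard error of single members (0.35, against 0.37 before). The camera adjusted p was 1.34e-11 at the fixed correlation of 0.01. Only 3 of 15 gene calls stayed, so a first rule, which also asked for called genes to stay, could not tell. A later rule on the median alone counted against erythroid cells as the whole source of the median. The macrophage score took that median to −0.63 (1.58 such standard errors, 0.40 against 0.37 before) and ended all 15 calls, so myeloid cells stay open there. For the marginal zone list the macrophage score left −1.18 of −1.53 (4.73 such standard errors, 0.25 against 0.21 before, camera adjusted p 6.41e-08). With 4 of 10 calls kept the first rule could not tell there either. The later rule counted against myeloid cells as the whole source of that median. Standard errors of single genes are not a spread of the list median, and in the main fit both list calls ended with an estimated correlation. The later rule therefore settles neither cause. A share of either shift from other cells stays open, as do the single genes that lost their call.

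LPS fl/fl replicate 2 shows raised signal at dim probes. More labelled RNA or a higher gain would raise all spots alike, but the dimmest 25% of genes rose by 0.62 more than the brightest 25%, which speaks against it. Cells of other types could raise genes that are dim in B cells: they would raise only part of the dim probes, under 50% by the bound set, but 75.5% of the probes dim on both other LPS fl/fl arrays were more than 1 log2 unit higher. The bound against this was 75%, but probes of 1 array are not independent, so this stays open. Negative controls, matching no transcript, read 6.30 above the highest other array of the slide (largest standard deviation 1.92). The median spot rose more (93.0 against 32.1 and 34.2 on the other LPS fl/fl arrays). Unmatched signal may thus be only a part. Without that array 218 genes differed after LPS.

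Calls between the genotypes could come from a stretch of chromosome 11 carried over from the strain of the targeted allele. Within 20 Mb of Ebf1 26 of 330 genes were called in resting cells against 1461 of 16486 elsewhere (odds ratio 0.88, p 0.761), and 2 of 330 after LPS (odds ratio 0.35, p 0.978), so the calls are not enriched there. For the 2 genotype effects and the 2 LPS responses only 10 splits of the 6 arrays exist, too few for a share under 0.05: 1 split, the real one, reached 1510, 290, 9891 and 9524 genes, with 2, 8, 0 and 6 as the highest of the others.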

How the results depend on the processing

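With 3 arrays per group, 1 array can move the counts of the genotype effects by several fold, and slides and groups are only partly balanced. Gates, animals and the dose of LPS per sample are not given, and no cells without Cre were analysed here. The cause of each change in this section was not tested unless a test is named. Counting each named gene call under each setting chosen before the data were examined, 8280 stayed, 1182 weakened and 11 reversed sign, and for lists, by the direction of the list test, the numbers were 1518, 144 and 9. The covariates, the repaired normexp, the fit without resting +/fl 1 and 3 and the slide block without LPS fl/fl 2 were chosen after seeing the data, with 1484, 284 and 2 for genes and 262, 37 and 1 for lists. Both sets of numbers pool the genotype effects with the LPS responses, whose counts moved less. They do not measure how stable the genotype calls are.

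Counts of genes are given in the order resting genotype effect (1510), LPS genotype effect (290) and interaction (30). Normexp gave 0, 0 and 0, and in the LPS responses of +/fl and fl/fl cells 1484 and 2390 genes in place of 9891 and 9524. The repaired normexp gave 1643 resting and 411 LPS genotype genes (167 higher and 244 lower) and 11460 and 11223 genes in the LPS responses. No filter gave 421, 27 and 8. Without the 2 arrays that share a sample name number the counts were 276, 14 and 3. The macrophage score gave 73, 147 and 0, and an adjusted p below 0.01 gave 192, 15 and 5. The erythroid score gave 477 genes in the resting genotype effect and 17 in the interaction. In the resting genotype effect alone, leaving out resting +/fl 1 and 3 gave 86 (24 higher and 62 lower) and only the 6 arrays 134. At 2-fold or more 461 and 131 genotype genes and 5655 and 5272 LPS genes remained.

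In the LPS genotype effect quantile normalization and the deposited values gave 136 genes each, and only the 6 arrays 32. The slide block gave 5 there and 7 in the interaction, and with LPS fl/fl 2 left out as well 104 and 4. A filter on all 12 arrays gave 531 and 238, eBayes with trend and robust 642 and 424, and array weights 2728 and 326. In the interaction the mean over probes gave 7 and the repaired normexp 100. Leaving out 1 array at a time gave 504 to 1664 resting genotype genes, 16 to 292 after LPS, 8960 to 10269 and 8728 to 9574 in the LPS responses, and 8 to 140 in the interaction.

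Replicate number as a block gave 725, 42 and 9 genes and 22 shared genotype genes. It ended the calls of the Ebf1 probes, whose values (0.62 and −1.90) a block balanced over the groups cannot move. Correlations of arrays with the same number ran from −0.003 to 0.13 in the resting and −0.03 to 0.12 in the LPS genotype comparison, where the highest pair was a same-number pair each time, and from −0.08 to 0.06 and −0.07 to −0.05 in the LPS responses. Not every array correlated best with its own number, so the samples are taken to share only a replicate number. Resting +/fl 3 and LPS +/fl 1, which share a number in their sample names, may come from 1 animal. They correlated at 0.133, the highest of all pairs listed, and the labels do not settle this. The numbers of the resting fl/fl samples all lie below those of every other sample. What the numbers stand for is not given. If they follow animals or cohorts, neither the resting genotype effect nor the fl/fl LPS response can be told apart from them. The same holds for the interaction, which uses the resting fl/fl samples too.

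The Ebf1 probe for NM_007897 in resting cells (0.62) lost its call with normexp (0.50), without the arrays sharing a number (0.66), without resting +/fl 1 and 3 (0.34), with the macrophage (0.45) or erythroid score (0.60), and at an unchanged 0.62 with no filter, with the slide block with or without LPS fl/fl 2, and with only the 6 arrays. The AK036716 probe (−1.90) lost it in the same settings, at −0.49, −2.18, −2.31, −2.13 and −1.56 where the value moved and at −1.90 otherwise, and also with quantile normalization (−1.83), the deposited values (−1.92), array weights (−2.04) and the repaired normexp (−0.63). Leaving out 1 array gave 0.44 to 0.77 and −2.18 to −1.64 resting, and 0.08 to 0.17 and −1.54 to −0.50 after LPS. The mean over both probes was −0.64 (adjusted p 0.177), the reverse sign of the brighter one.

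The number of lists past the threshold (10, 14, 16, 11 and 9 over the 5 comparisons) was 0 in each with an estimated correlation, and 18 in the interaction with normexp. Leaving out 1 array gave 9 to 13, 12 to 16, 15 to 17, 11 to 13 and 6 to 10. Signs reversed without resting +/fl 1 and 3 for interferon genes (0.059) and T cell markers (0.41) in resting cells. In the LPS genotype effect they reversed with normexp for B-lineage (0.066), BCR (0.30), ER chaperone (0.29), NF-kB (0.42), MYC (0.21), cholesterol (0.15), glycolysis (0.051) and stromal lists (−0.59), and for ER chaperones with quantile normalization (0.0013) and deposited values (0.0012). In the interaction normexp reversed ER chaperone (0.16), NF-kB (0.19), cholesterol (0.18) and glycolysis lists (0.22), and the macrophage score reversed the cell cycle list (−0.39). Some medians of called lists turned while the direction of the test did not, so they are not among the reversals counted above. These were B-lineage genes after LPS with the slide block without LPS fl/fl 2 (0.006), and dendritic markers after LPS (−0.34) and stromal markers in the interaction (−0.50) with normexp. Myeloid markers turned in the +/fl LPS response with the filter on all 12 arrays (0.088), the macrophage (0.38) and the erythroid score (0.22), and in the interaction with the macrophage score (−0.03). ER chaperones turned in the interaction with quantile normalization (0.06) and the deposited values (0.05).

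Among genes, normexp reversed Krt2 (−0.11), Mroh2b (−0.32), Chil5 (−0.51), Mroh3 (−0.27), Pir (−0.10) and Klrk1 (−0.34) in the LPS genotype effect, Ticam2 in the LPS responses of +/fl (−0.071) and fl/fl cells (−0.91), and Tfr2 (−0.22) and Tlr3 (−0.29) in the interaction. In the repaired normexp all 290 LPS genotype genes and all 30 interaction genes kept their sign, and 222 and 27 their call. It gave Krt2 0.88, Mroh2b 0.73, Chil5 0.53, Mroh3 0.66, Pir 0.79, Klrk1 0.59, Tlr3 0.92 and Tfr2 1.06, and left Ticam2 at −0.042 and −0.13.

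Of 82 genes shared by the genotype effects, 0 remained with normexp, 11 with no filter, 3 with the slide block, 6 without the arrays sharing a number, 11 without resting +/fl 1 and 3, 11 with the macrophage and 42 with the erythroid score, 7 at an adjusted p below 0.01 and 29 at 2-fold or more. The filter on all 12 arrays gave 146, trend and robust 169, array weights 359, and leaving out 1 array 11 to 94. The correlation of 0.15 became 0.34 with the slide block without LPS fl/fl 2 and 0.08 to 0.27 without 1 array. Of 7677 genes shared by the LPS responses 1325 remained with normexp and 4026 at 2-fold or more, and 7064 to 7750 without 1 array. Their correlation of 0.831 became 0.731 with no filter, 0.898 with the filter on all 12 arrays, 0.911 with the repaired normexp, and 0.791 to 0.861 without 1 array.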

Other observations

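The genes here were chosen after their values were seen, so they test no theme. The first 4 genes picked read lower in fl/fl cells both resting and after LPS. Scd1 and Scd2, which put the first double bond into saturated fatty acids, read −2.04 and −1.46 resting (adjusted p 0.000263 and 0.00733) and −0.80 and −1.17 after LPS (adjusted p 0.0368 and 0.0353). Sema7a, a membrane-anchored semaphorin, read −1.87 and −1.61, and Wnt10a, a Wnt ligand, −2.34 and −1.38. Higher in both states were Cd7 (0.68 and 1.41) and Cd55b, a complement regulator (1.07 and 0.98).

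Chosen the same way, Tk1, the thymidine kinase of S phase, read −1.38 and −1.06 (adjusted p 0.00321 and 0.0202), Gmnn, geminin, −1.10 and −1.06 (0.00715 and 0.0202), and Pttg1, securin, −1.17 and −1.40 (0.00375 and 0.00524). These 3 genes test nothing, since they were picked for their values. As a hypothesis, fl/fl cells may divide less in both states. The cell cycle median after LPS was −0.78, a call that ended with an estimated correlation (adjusted p 0.353). Myeloid markers were not lower there (0.75, 0.48 without LPS fl/fl replicate 2 and 0.42 with slide as a block as well), but erythroid markers read −0.62, and −1.36 without LPS fl/fl replicate 2 (adjusted p 0.025), the direction that cell mixture needs. The resting median shrank to −0.63 with the macrophage score as a covariate, so mixture stays open. Counting divisions by dye dilution in sorted cells would separate the accounts.

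A second hypothesis is that the fl/fl cells held fewer CD21-high cells because of how they were sorted. The labels name a CD21lo gate, and Cr2 differed by −2.46 resting and −1.98 after LPS. The marginal zone median was −1.18 with the macrophage score, where 4 of 10 gene calls stayed, and only the gate of each sample could decide whether sorting is the likely source.

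Targets of p53 rose with LPS in both genotypes (2.87 and 3.13), with 11 and 12 of 14 members higher and 1 lower in each, and both calls ended with an estimated correlation (adjusted p 0.203 and 0.16), while the cell cycle list was not called in either. Resting and LPS cells had the same tamoxifen treatment per the labels, so an effect of Cre that is alike in both states cancels in these values.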
